A study of Arabidopsis thaliana with 27 samples.

How the data were processed

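RNA-seq read counts of 27 libraries from stamens and gynoecia were analysed, as deposited raw reads per TAIR locus (33602 loci in each library). Per the submitters' notes, TopHat2, HTSeq and edgeR were used with the TAIR10 build, with versions, strand setting and order of steps not given. Per the labels, the libraries were made from messenger RNA with a TruSeq kit and read as single-end reads of 50 bases on a HiSeq instrument. Groups follow the sample titles, with tissue, genotype and replicate number. In the stamen mARF8 and arf6axr3 groups the genotype tags give the same line for each library while titles give others, and titles were used. A reference table of TAIR10.1 genes served only for names and neighbours, and matched 32835 loci, 10654 of them with a symbol.

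Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Loci were filtered with filterByExpr (minimum count 10, minimum total 15) by group, scaled by TMM and fitted with edgeR's quasi-likelihood model, with 1 fit per tissue. The stamen fit held 18828 loci in 9 libraries with 6 residual degrees of freedom and a biological coefficient of variation of 0.227, and the gynoecium fit 18616 loci in 18 libraries with 13 and 0.117. Differences between tissues came from a fit of the 27 libraries as an interaction. All gene p-values are edgeR quasi-likelihood F test p-values adjusted by Benjamini and Hochberg over the genes of a comparison, called under 0.05, with SE taken as the log2 fold change over the root of F. Mean log2 CPM of lists used a prior count of 2. At 3 counts a library's CPM ranged from 0.195 to 0.812, the precision that its depth gives near 0. A ratio with 1 to 3 counts in a group has a 95% counting interval.

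Before the data were examined, the comparisons, the 19 gene lists with 415 memberships, the named-gene rule and the first set of alternatives were fixed. Named genes are the altered genes, the 5 highest and 5 lowest called genes with an average log2 CPM of at least 1 and no overlap between the groups' libraries, and 2 members with the smallest adjusted p of each list with at least 3 called. For differences between tissues the 3 highest and lowest were named. The reference table gives 1 list member the symbol of another gene, and it was left out before any list was tested. Lists were tested with limma's camera on the 171 list and comparison pairs with a preset correlation of 0.01, which called 54, and with the correlation estimated per list, which called 1. In 25 pairs the signs of median, mean and test differ.

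Alternatives fixed beforehand were median-of-ratios and upper-quartile factors, the DESeq2 Wald test, no filter, a stricter filter of 5 CPM, only the groups compared, the replicate number as a further term, single transgenic lines, an estimated correlation for the list test and leaving out each library in turn. Chosen after seeing the data were the library number as a covariate, low-numbered libraries only (up to 23), high-numbered libraries only (from 26) and, for the tissue difference of mARF8, stamens of line 3B only. Low and high refer to the library numbers in the sample labels. The same functions were tested on simulated data with 200 changed genes per comparison. Genes changed 2-fold were found in 16.9% of cases for arf6arf8 stamens, 32.1% for mARF8 stamens and 81.0 to 88.1% in gynoecia, genes changed 4-fold in 69.0, 84.2 and 98.3%, and false calls made up 1.21 to 6.63% of calls. For overlaps, 20 sets of unchanged groups with shared controls were simulated, and the wild-type gynoecium libraries were divided between the comparisons.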

Results

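Polyadenylated RNA was sequenced from stamens and gynoecia of Arabidopsis thaliana with altered ARF6 and ARF8 activity. ARF6 and ARF8 are auxin response factors, transcription factors whose transcripts are targets of the microRNA miR167. The 27 libraries fell into 8 groups. Stamens, from stage 11 buds, gave wild type (n = 3), the arf6 arf8 double mutant (n = 2, here arf6arf8) and mARF8 plants (n = 4), which carry a genomic ARF8 transgene with a mutated miR167 site. Gynoecia, from stage 12 flowers, gave wild type (n = 4), arf6arf8 (n = 2), mARF8 (n = 4), axr3 (n = 4) and arf6axr3 (n = 4). Plants called axr3 expressed a stabilised form of the auxin response repressor IAA17 from the promoter of the ovule identity gene STK, and arf6axr3 plants carried that transgene in an arf6 mutant. By title, mARF8 stamens 1 and 3 were line 3B, 2 was line 4B and 4 a pool of T1 plants, and mARF8 gynoecia were line 3B. For axr3, 3 was line 15-5, 4 an F1 of wild type and line 25-2, and 1 and 2 name no line, and for arf6axr3, 1 and 3 were line 15-5 and 2 and 4 line 25-2. Total counts per library ran from 3989223 to 5512416 in wild-type stamens, 9718773 to 12723197 in arf6arf8 stamens and 5125510 to 10104891 in mARF8 stamens. In gynoecia they ran from 6177301 to 11821613 in wild type, 14586768 to 15005992 in arf6arf8, 3692975 to 7017884 in mARF8, 5221673 to 11066943 in axr3 and 7291701 to 15374607 in arf6axr3. Values below are means ± SD over these replicates of CPM (read counts scaled to the size of the library), tests are edgeR quasi-likelihood tests, and libraries are written as group and replicate number. The labels do not say whether replicates came from separate plants, so the p-values measure spread between these samples, which may be technical. Where a gene had no count in a group, its fold is a bound against 3 counts over that group. Bounds and intervals of this kind cover counting error only.

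The altered genes were measured in every library first. ARF6 (AT1G30330) stood at 21.5 and 24.1 CPM in arf6arf8 stamens against 83.6 to 94.3 in wild type, and at 131 and 140 CPM in arf6arf8 gynoecia against 437 to 562. ARF8 (AT5G37020) stood at 18.1 and 19.3 CPM in arf6arf8 stamens against 55.9 to 74.6 in wild type, and at 87.4 and 91.9 CPM in arf6arf8 gynoecia against 371 to 406. In mARF8 replicates 1 to 4, ARF8 stood at 483, 504, 263 and 463 CPM in stamens and at 788, 1088, 1185 and 1217 CPM in gynoecia. IAA17 (AT1G04250) lay at 68.3 to 84.9 CPM in axr3, 26.6 to 36.0 in arf6axr3 and 8.10 to 14.3 in wild-type gynoecia, and ARF6 lay at 55.7 to 61.8 CPM in arf6axr3. Each of these libraries thus stood on the side of wild type that its label gives. Reads of the transgenes and of the endogenous ARF8 and IAA17 genes cannot be told apart here. STK (AT4G09960) stood in replicates 1 to 4 at 92.7, 60.8, 104 and 45.7 CPM in axr3 and 157, 31.8, 159 and 35.5 CPM in arf6axr3, against 129 to 138 in wild-type gynoecia. The miR167 primary transcript locus MIR167a (AT3G22886) stood at 16.4 and 16.1 CPM in arf6arf8 gynoecia against 0.159 to 0.547 in wild type, and at 7.60 and 9.83 CPM in arf6arf8 stamens against 1.24 to 2.83. MIR167b (AT3G63375) reached 0.941 CPM at most in any library, MIR167c (AT3G04765) was listed at 0 in the 27 libraries, and MIR167d (AT1G31173) had 1 count, in mARF8 stamens 3.

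**Figure D1:**
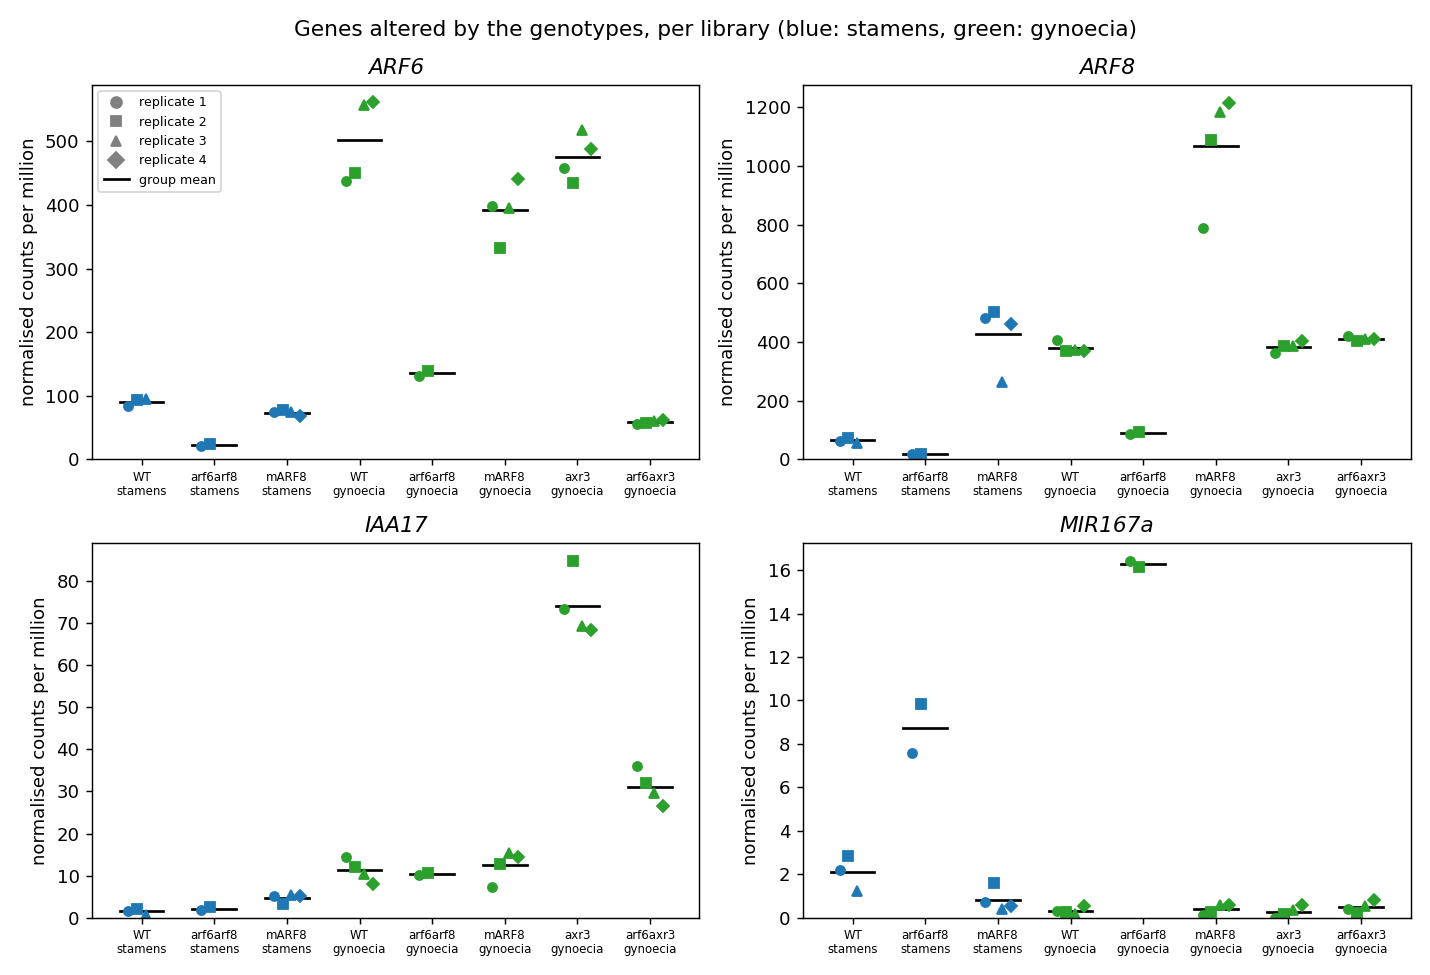
Normalised CPM (vertical axes) of ARF6, ARF8, IAA17 and MIR167a in each library of the 8 groups (horizontal axes). ARF8 in mARF8 stamens 3 sits at 263 CPM, below the other mARF8 stamen libraries and above the wild-type stamen range of 55.9 to 74.6.

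In arf6arf8 stamens, transcripts of jasmonate response and jasmonate synthesis were lower than in wild type, together with flavonoid and cuticle genes. MYB21 (AT3G27810) and MYB24 (AT5G40350), MYB transcription factors of stamen growth, were close to absent. MYB21 was at 0.205 ± 0.149 against 41.2 ± 5.96 CPM (log2 fold change −7.45, SE 0.55, adjusted p = 0.000461), and MYB24 had no count in arf6arf8 and was at least 129-fold lower (adjusted p = 0.00124). Of 22 jasmonate response genes, 10 fell (13 lower adjusted over the list alone, camera adjusted p = 6.84e-21, or 0.102 with an estimated correlation). The jasmonate response count was 4 without arf6arf8 1. The jasmonate repressor gene JAZ8 (AT1G30135) fell by 2.88 (SE 0.24, adjusted p = 0.000663) on the log2 scale. Of 20 jasmonate synthesis genes, 5 fell (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 8.08e-06, or 0.206 with an estimated correlation). The jasmonate synthesis count was 1 without arf6arf8 1 and 3 without wild type 1 or 3 or arf6arf8 2. The lipoxygenase gene LOX2 (AT3G45140) was at 28.8 ± 9.74 against 1019 ± 46.3 CPM (log2 fold change −5.15, SE 0.38, adjusted p = 0.000452), and the allene oxide cyclase gene AOC1 (AT3G25760) was lower by a ratio of 88.7 (95% counting interval 15.2 to 3572, adjusted p = 0.00652). Of 10 flavonoid synthesis genes, 3 fell (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00128, or 0.553 with an estimated correlation). The flavonoid synthesis count was 0 without arf6arf8 1 and 1 without wild type 1 or 2 or arf6arf8 2. The chalcone synthase gene CHS (AT5G13930) was at 99.2 ± 26.0 against 480 ± 60.0 CPM (log2 fold change −2.27, SE 0.41, adjusted p = 0.0176), and the flavonol regulator gene MYB12 (AT2G47460) fell by 3.69 (SE 0.45, adjusted p = 0.00314). Of 26 cuticle genes, 4 fell (4 lower adjusted over the list alone, camera adjusted p = 0.0292, or 0.790 with an estimated correlation). The cuticle count was 0 without arf6arf8 1 and 2 without wild type 1 or 2 or arf6arf8 2. The cuticle regulator gene SHN3 (AT5G25390) fell by 3.16 (SE 0.38, adjusted p = 0.00278) and AT5G33370 by 2.38 (SE 0.31, adjusted p = 0.00426). AOC1 (0.0905), MYB12 (0.0535), SHN3 (0.0585) and AT5G33370 (0.0757) lost their calls without arf6arf8 1, highest adjusted p in brackets. CHS (0.195) lost its call without wild type 1 or 2 or arf6arf8 1 or 2.

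The highest genes of arf6arf8 stamens by log2 fold change were AT4G21630 at 5.56 (SE 0.48, adjusted p = 0.000884), SVL3 (AT3G20520) at 5.00 (SE 0.30, adjusted p = 0.000244), AT1G62500 at 3.93 (SE 0.40, adjusted p = 0.00149), AT5G67620 at 3.77 (SE 0.61, adjusted p = 0.0111) and AT3G04320 at 3.77 (SE 0.34, adjusted p = 0.000984). Besides MYB24, the lowest had no count in arf6arf8. The suberin acyltransferase gene GPAT5 (AT3G11430) was at least 285-fold lower (adjusted p = 0.00380), MIF2 (AT3G28917) at least 193-fold (adjusted p = 0.00489), and the glycosyltransferase genes UGT85A3 (AT1G22380) and UGT85A1 (AT1G22400), similar copies that may share reads, at least 129-fold (adjusted p = 0.00997) and 97.0-fold (adjusted p = 0.00729). MIR167a rose, with log2 fold change 2.02, SE 0.44, adjusted p = 0.0368, and ARF6 and ARF8 fell by 1.98 (SE 0.12, adjusted p = 0.000244) and 1.80 (SE 0.28, adjusted p = 0.00965). Of 27 photosynthesis genes, 2 fell (9 lower adjusted over the list alone, camera adjusted p = 2.98e-07, or 0.618 with an estimated correlation). The photosynthesis count was 1 without wild type 1 or 2 or arf6arf8 1 or 2. Of 13 tapetum and pollen wall genes, 2 rose (6 higher adjusted over the list alone, camera adjusted p = 5.66e-05, or 0.259 with an estimated correlation). The tapetum count was 0 without wild type 1 or 3 or arf6arf8 1 or 2 and 1 without wild type 2. Of 26 late pollen and sperm genes, 1 fell (4 lower adjusted over the list alone, camera adjusted p = 0.000247, or 0.790 with an estimated correlation). The late pollen count was 0 without arf6arf8 1. The list mean stood at −1.16 and −1.14 in arf6arf8 1 and 2 relative to wild type. Of 23 secondary wall genes edgeR called 0, with 10 higher and 0 lower at unadjusted p < 0.05 and 0 higher and 0 lower by DESeq2 (median log2 fold change 0.69, camera adjusted p = 0.000345, or 0.686 with an estimated correlation). Of 7 floral terpene genes edgeR called 0, with 1 higher and 4 lower at unadjusted p < 0.05 and 1 higher and 4 lower by DESeq2 (median log2 fold change −2.40, camera adjusted p = 0.0271, or 0.634 with an estimated correlation). The heat shock mean, a sign of handling, stood 0.85 and 1.29 above wild type. In all, 826 of 18828 genes changed, 253 higher and 573 lower. The low-numbered libraries alone gave 287 genes, no arf6arf8 stamen library has a high number, DESeq2 gave 1375, and fitting only the groups compared gave 3530. The count was 99 without arf6arf8 1, 169 without arf6arf8 2, 359 without wild type 1, 450 without wild type 3 and 464 without wild type 2. AT5G67620 (0.0969), UGT85A3 (0.103), UGT85A1 (0.0772) and ARF8 (0.128) lost their calls without arf6arf8 1 or 2, highest adjusted p in brackets. GPAT5 (0.0502) and MIF2 (0.0590) lost their calls without arf6arf8 1. MIR167a (0.276) lost its call without wild type 1, 2 or 3 or arf6arf8 1 or 2.

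In mARF8 stamens, transcripts of late pollen and sperm were lower than in wild type, and transcripts of the tapetum, the secondary wall of the endothecium, the cuticle and photosynthesis were higher. Of 26 late pollen genes, 23 fell (24 lower adjusted over the list alone, camera adjusted p = 9.67e-12, or 0.553 with an estimated correlation). The late pollen count was 10 without wild type 1 or 3, 14 without mARF8 1 and 15 without wild type 2 or mARF8 4. STP11 (AT5G23270), a sugar transporter gene of pollen, was at 0.293 ± 0.388 against 16.9 ± 4.48 CPM (log2 fold change −5.49, SE 0.60, adjusted p = 0.000997), and AT4G33970 was at 1.26 ± 1.72 against 33.1 ± 4.64 CPM (log2 fold change −4.45, SE 0.66, adjusted p = 0.00282). Relative to the wild-type mean, the mean log2 CPM of this list was −2.63, −3.80, −1.20 and −2.28 in mARF8 1 to 4, and ARF8 was lowest in mARF8 3. Of 13 tapetum genes, 8 rose (10 higher adjusted over the list alone, camera adjusted p = 0.000356, or 0.259 with an estimated correlation). The tapetum count was 3 without wild type 1 or 3. AMS (AT2G16910), a transcription factor gene of the tapetum, was at 131 ± 22.1 against 47.6 ± 7.43 CPM (log2 fold change 1.47, SE 0.16, adjusted p = 0.00108), and AT1G75910 rose by 1.91 (SE 0.25, adjusted p = 0.00196) on the log2 scale. Of 23 secondary wall genes, 14 rose (16 higher adjusted over the list alone, camera adjusted p = 3.92e-05, or 0.618 with an estimated correlation). The secondary wall count was 5 without wild type 1 or 3. MYB26 (AT3G13890), a regulator of endothecium thickening, was at 50.9 ± 14.2 against 9.24 ± 2.68 CPM (log2 fold change 2.46, SE 0.27, adjusted p = 0.00108), and NST1 (AT2G46770), a NAC factor gene of secondary walls, rose by 1.88 (SE 0.20, adjusted p = 0.000971). Of 26 cuticle genes, 15 rose and 2 fell (15 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.28e-05, or 0.553 with an estimated correlation). The cuticle count was 1 lower without wild type 1 or mARF8 1. The cutin gene CYP86A7 (AT1G63710) rose by 2.22 (SE 0.27, adjusted p = 0.00140) and the wax gene KCS6 (AT1G68530) by 1.80 (SE 0.23, adjusted p = 0.00162). Of 27 photosynthesis genes, 16 rose (20 higher adjusted over the list alone, camera adjusted p = 0.000352, or 0.795 with an estimated correlation). The photosynthesis count was 0 without wild type 3, 6 without wild type 1, 9 without wild type 2 and 10 without mARF8 1. The Rubisco small subunit gene RBCS1A (AT1G67090) rose by 0.79 (SE 0.18, adjusted p = 0.0133) and the light-harvesting gene LHCB5 (AT4G10340) by 0.89 (SE 0.20, adjusted p = 0.0127). Of 8 heat shock genes, 1 rose (0 adjusted over the list alone, camera adjusted p = 0.217). The heat shock count was 0 without wild type 1, 2 or 3 or mARF8 1, 2 or 4 and 6 without mARF8 3. The mean of this list, a sign of handling, stood 1.46, 3.50, 0.08 and 1.12 above wild type in mARF8 1 to 4, ranking them as the late pollen fall does. RBCS1A (0.0679) and LHCB5 (0.0616) lost their calls without wild type 3, highest adjusted p in brackets.

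**Figure D2:**
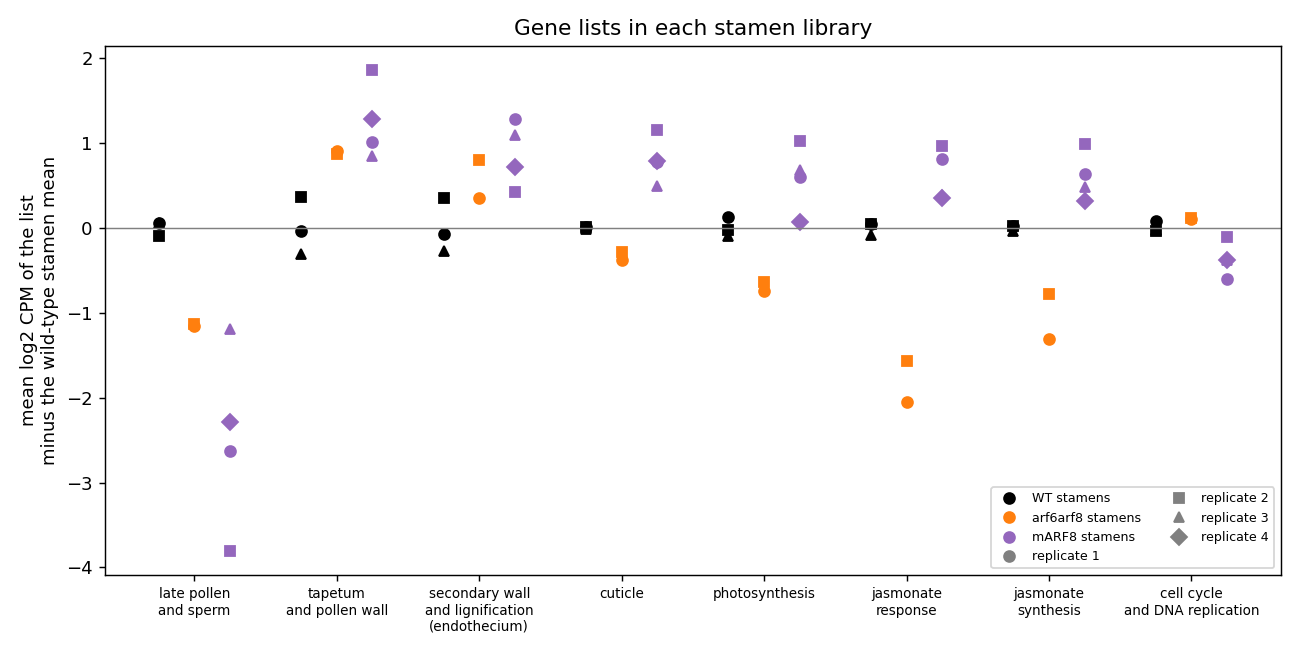
Mean log2 CPM of 8 gene lists in each stamen library minus the wild-type stamen mean (vertical axis), by list (horizontal axis). The late pollen list sits at −3.80 to −1.20 in the mARF8 libraries and at −0.10 to 0.05 in the wild-type libraries.

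Hormone genes of mARF8 stamens changed in both directions. Of 22 jasmonate response genes, 10 rose and 1 fell (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0985). The jasmonate response count was 4 higher without wild type 1, 5 higher without mARF8 1 and 6 higher without wild type 2 or 3. JAZ8 was at 14.8 ± 0.696 against 4.98 ± 0.259 CPM (log2 fold change 1.57, SE 0.16, adjusted p = 0.000769), and MYB108 (AT3G06490), a MYB gene of stamen maturation, was at 0.484 ± 0.542 against 13.8 ± 4.55 CPM (log2 fold change −4.57, SE 0.55, adjusted p = 0.00144). Of 20 jasmonate synthesis genes, 10 rose and 4 fell (11 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0519). The jasmonate synthesis count was 4 higher without wild type 1 and 6 higher without wild type 2 or 3, and 0 lower without wild type 1 or 3 or mARF8 1 or 4 and 1 lower without wild type 2. LOX2 was at 3077 ± 759 against 1019 ± 46.3 CPM (log2 fold change 1.60, SE 0.26, adjusted p = 0.00375), and LOX6 (AT1G67560) rose by 1.10 (SE 0.21, adjusted p = 0.00656). Of 28 Aux/IAA and GH3 genes, 10 rose and 3 fell (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0985). The Aux/IAA and GH3 count was 6 higher without wild type 1. IAA7 (AT3G23050), which encodes an Aux/IAA repressor, was at 74.8 ± 30.5 against 8.92 ± 0.847 CPM (log2 fold change 3.06, SE 0.34, adjusted p = 0.00105), and IAA11 (AT4G28640) rose by 1.99 (SE 0.25, adjusted p = 0.00161). SWEET14 (AT4G25010), a sugar transporter gene of anthers, was at 0.359 ± 0.194 against 15.7 ± 10.8 CPM (log2 fold change −5.47, SE 0.60, adjusted p = 0.00103). Of 30 cell cycle genes, 7 fell (6 lower adjusted over the list alone, camera adjusted p = 0.0285, or 0.553 with an estimated correlation). The cell cycle count was 3 without wild type 3 and 4 without wild type 1 or mARF8 1. The Aurora kinase genes AUR1 (AT4G32830) and AUR2 (AT2G25880) fell by 1.57 (SE 0.29, adjusted p = 0.00618) and 1.38 (SE 0.26, adjusted p = 0.00619).

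Among smaller lists of mARF8 stamens, of 4 female gametophyte genes, 1 rose (1 higher adjusted over the list alone, camera adjusted p = 0.586). The female gametophyte count was 0 without wild type 1 or 3 and 2 without mARF8 3. Of 14 clock genes, 1 rose and 2 fell (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.674). The clock count was 0 higher without wild type 2 or 3 or mARF8 1 and 2 higher without mARF8 4, and 0 lower without wild type 1 or 3 or mARF8 1 and 1 lower without wild type 2 or mARF8 4. The clock gene LHY (AT1G01060) rose by 1.06 (SE 0.30, adjusted p = 0.0257) and LUX (AT3G46640) fell by 1.13 (SE 0.30, adjusted p = 0.0200). AT2G17845, MYB57 (AT3G01530), AT4G36430, ANN6 (AT5G10220) and AT5G64120 had no count in wild type and were at least 86.2-fold (adjusted p = 0.00464), 45.0-fold (adjusted p = 0.0183), 115-fold (adjusted p = 0.0171), 43.5-fold (adjusted p = 0.0451) and 21.1-fold (adjusted p = 0.0371) higher. CYP79F1 (AT1G16410) and BCAT4 (AT3G19710), genes of glucosinolate synthesis from methionine, had no count in mARF8 and were at least 89.0-fold (adjusted p = 0.00883) and 83.4-fold (adjusted p = 0.00886) lower. UGT73C2 (AT2G36760) was lower by a ratio of 132 (95% counting interval 35.9 to 1105, adjusted p = 0.000537) and LTI30 (AT3G50970) by 147 (95% counting interval 25.5 to 5883, adjusted p = 0.00812), and GPAT5 fell by 7.41 (SE 0.75, adjusted p = 0.00108). ARF8 rose by 2.72 (SE 0.24, adjusted p = 0.000472) and IAA17 by 1.61 (SE 0.36, adjusted p = 0.0120), and ARF6 and MIR167a fell by 0.29 (SE 0.09, adjusted p = 0.0373) and 1.45 (SE 0.49, adjusted p = 0.0465). In all, 6961 of 18828 genes changed, 3838 higher and 3123 lower. The higher share was 55.1%, but 47.3% with median-of-ratios factors, 47.5% with DESeq2, 46.0% with line 3B alone, 48.4% without mARF8 2 and 45.3% without wild type 3, so neither direction prevails. In the low-numbered stamen libraries 1325 genes changed, and the high-numbered stamen libraries, 1 wild type and 1 mARF8, give no fit. The count was 2895 without wild type 3 and 3210 without wild type 1, and 8789 without mARF8 3. LHY (0.105) lost its call without wild type 2 or 3 or mARF8 1, highest adjusted p in brackets. LUX (0.0675) lost its call without wild type 1 or 3 or mARF8 1. MYB57 (0.0541) and AT4G36430 (0.0530) lost their calls without wild type 3. ANN6 (0.103) lost its call without wild type 1, 2 or 3 or mARF8 1, 2 or 4. AT5G64120 (0.0915) and ARF6 (0.0924) lost their calls without wild type 1, 2 or 3 or mARF8 1 or 4. MIR167a (0.174) lost its call without wild type 1, 2 or 3 or mARF8 1, 3 or 4.

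Across the 2 stamen comparisons, JAZ8 and LOX2 fell in arf6arf8 and rose in mARF8, whereas GPAT5 was lower in both. Of the 18828 genes tested, 301 changed in the same direction and 190 in opposite directions. There were 97 genes higher in both, against 51.6 for independent lists of those sizes, and 204 lower in both. Higher in arf6arf8 and lower in mARF8 were 27, against 42.0, and lower in arf6arf8 and higher in mARF8 were 163, against 117. Both comparisons share the wild-type libraries (covariance of the fold changes across genes 0.358, and 0.0631 simulated). Genes are not independent replicates, and with 3 wild-type libraries the controls could not be divided. The low-numbered libraries alone gave 57 in the same and 33 in opposite directions, and the counts were 24 and 38 without arf6arf8 1, 46 and 61 without arf6arf8 2, 77 and 65 without wild type 1, 175 and 85 without wild type 2 and 111 and 80 without wild type 3.

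In arf6arf8 gynoecia, SAUR and carpel regulator genes were lower than in wild type, and MIR167a was higher. MIR167a was at 16.3 ± 0.203 against 0.313 ± 0.166 CPM (log2 fold change 5.61, SE 0.41, adjusted p = 2.14e-07). Of 9 SAUR genes, 5 fell (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00588, or 0.355 with an estimated correlation). The SAUR count was 2 without arf6arf8 1 and 3 without wild type 1, 2 or 4 or arf6arf8 2. AT5G18030 was lower by a ratio of 23.3 (95% counting interval 6.18 to 197, adjusted p = 0.000189) and SAUR67 (AT1G29510) fell by 2.26 (SE 0.36, adjusted p = 0.000444), and reads of such tandem copies may be shared. Of 29 Aux/IAA and GH3 genes, 4 rose and 7 fell (5 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.128). The Aux/IAA and GH3 count was 1 higher without arf6arf8 1 and 2 higher without wild type 2 or 4, and 3 lower without arf6arf8 1 and 4 lower without wild type 1. IAA7 was at 2.84 ± 0.553 against 34.4 ± 7.24 CPM (log2 fold change −3.60, SE 0.30, adjusted p = 7.19e-07), and IAA26 (AT3G16500) fell by 1.37 (SE 0.14, adjusted p = 7.53e-06). Of 21 carpel, style and transmitting tract genes, 1 rose and 7 fell (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00100, or 0.102 with an estimated correlation). The carpel count was 0 higher without arf6arf8 1, and 4 lower without arf6arf8 1 or 2. IND (AT4G00120) and SHP1 (AT3G58780), transcription factor genes of the valve margin, were at 0.917 ± 0.605 against 9.55 ± 3.70 CPM (log2 fold change −3.37, SE 0.49, adjusted p = 0.000187) and 89.2 ± 14.8 against 148 ± 6.11 CPM (log2 fold change −0.73, SE 0.09, adjusted p = 6.57e-05). Of 9 ovule and integument genes, 1 fell (1 lower adjusted over the list alone, camera adjusted p = 0.0156, or 0.553 with an estimated correlation). Of 10 flavonoid synthesis genes, 3 fell (4 lower adjusted over the list alone, camera adjusted p = 0.0269, or 0.688 with an estimated correlation). The flavonoid synthesis count was 1 without arf6arf8 2. MYB12 fell by 1.24 (SE 0.23, adjusted p = 0.00161) and MYB11 (AT3G62610) by 1.15 (SE 0.26, adjusted p = 0.00729). Of 19 secondary wall genes, 3 rose (7 higher adjusted over the list alone, camera adjusted p = 0.00274, or 0.461 with an estimated correlation). The secondary wall count was 0 without arf6arf8 1 and 6 without wild type 1. NST1 rose by 1.64 (SE 0.40, adjusted p = 0.0132) and TBL29 (AT3G55990) by 1.61 (SE 0.42, adjusted p = 0.0192). Anther lists were not called but stood above wild type in arf6arf8 1 and 2, tapetum by 0.72 and 0.85 (camera adjusted p = 0.531, wild-type libraries −0.62 to 0.57) and late pollen by 0.38 and 1.02 (camera adjusted p = 0.459), and stamen material in these libraries is not excluded. MYB11 (0.126) lost its call without arf6arf8 2, highest adjusted p in brackets. NST1 (0.333) and TBL29 (0.277) lost their calls without arf6arf8 1.

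Among the highest genes of arf6arf8 gynoecia, the glutathione transferase gene GSTF6 (AT1G02930) was at 60.3 ± 15.1 against 0.117 ± 0.0862 CPM (log2 fold change 8.96, SE 0.83, adjusted p = 2.11e-06), AT1G06100 and AT3G55920 rose by 5.33 (SE 0.43, adjusted p = 5.33e-07) and 4.95 (SE 0.46, adjusted p = 2.16e-06), and AT4G08093 was higher by a ratio of 141 (95% counting interval 47.7 to 685, adjusted p = 0.000100). Among the lowest, AT3G26140 was at 0.375 ± 0.135 against 136 ± 21.5 CPM (log2 fold change −8.44, SE 0.35, adjusted p = 1.3e-10) and BETAG4 (AT5G20330) at 0.273 ± 0.0895 against 38.9 ± 9.06 CPM (log2 fold change −7.07, SE 0.60, adjusted p = 7.19e-07). GRI (AT1G53130) had no count in arf6arf8 and was at least 104-fold lower (adjusted p = 0.000348), and AT4G33600 and AT4G35160 were lower by ratios of 333 (95% counting interval 59.4 to 13176, adjusted p = 5.38e-08) and 534 (95% counting interval 95.6 to 21132, adjusted p = 2.14e-07). ARF6 and ARF8 fell by 1.89 (SE 0.12, adjusted p = 5.21e-08) and 2.08 (SE 0.13, adjusted p = 3.23e-08). In all, 2077 of 18616 genes changed, 1151 higher and 926 lower. Low-numbered libraries alone gave 1315 genes, and no arf6arf8 gynoecium library has a high number. The count was 753 without arf6arf8 2 and 792 without arf6arf8 1.

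In mARF8 gynoecia few genes changed, although ARF8 rose, at 1070.0 ± 195 against 380.0 ± 17.3 CPM (log2 fold change 1.49, SE 0.10, adjusted p = 1.84e-07). IAA7 was at 72.0 ± 15.5 against 34.4 ± 7.24 CPM (log2 fold change 1.04, SE 0.18, adjusted p = 0.0119), and IAA13 (AT2G33310) fell by 0.41 (SE 0.08, adjusted p = 0.0212). Among 21 carpel genes, 1 fell (5 lower adjusted over the list alone, camera adjusted p = 0.00140, or 0.102 with an estimated correlation). The carpel count was 0 without mARF8 3. Among 21 jasmonate synthesis genes, 1 rose (4 higher adjusted over the list alone, camera adjusted p = 0.000396, or 0.423 with an estimated correlation). The jasmonate synthesis count was 0 without wild type 4 or mARF8 3. Of 15 jasmonate response genes edgeR called 0, with 7 higher and 0 lower at unadjusted p < 0.05 and 2 higher and 0 lower by DESeq2 (median log2 fold change 0.52, camera adjusted p = 3.69e-07, or 0.331 with an estimated correlation). Of 19 secondary wall genes edgeR called 0, with 8 higher and 0 lower at unadjusted p < 0.05 and 3 higher and 0 lower by DESeq2 (median log2 fold change 0.57, camera adjusted p = 2.66e-05, or 0.259 with an estimated correlation). The peroxidase gene PRXCB (AT3G49120) rose by 1.75 (SE 0.22, adjusted p = 0.000890), scpl35 (AT5G08260) by 1.81 (SE 0.22, adjusted p = 0.000642) and AT2G43610 by 1.65 (SE 0.17, adjusted p = 0.000232). UMAMIT42 (AT5G40210) and AT1G14120 rose by 1.92 (SE 0.43, adjusted p = 0.0459) and 2.85 (SE 0.55, adjusted p = 0.0195). The aquaporin gene NLM1 (AT4G19030) was at 0.272 ± 0.251 against 3.70 ± 1.11 CPM (log2 fold change −3.59, SE 0.45, adjusted p = 0.000803), GILT (AT4G12960), AT2G34700 and MSRB9 (AT4G21850) fell by 3.66 (SE 0.81, adjusted p = 0.0439), 2.71 (SE 0.32, adjusted p = 0.000642) and 1.94 (SE 0.36, adjusted p = 0.0147), and AT1G28660 was lower by a ratio of 31.1 (95% counting interval 5.35 to 1250.0, adjusted p = 0.0357). In all, 128 of 18616 genes changed, 55 higher and 73 lower, and DESeq2 gave 335. Low-numbered libraries alone gave 3 genes and the high-numbered, with 1 mARF8 library, 1. With the library number as a covariate, chosen after seeing the data, 246 genes changed. The count was 38 without mARF8 3, 52 without wild type 4, 67 without mARF8 2 and 68 without wild type 2. IAA7 (0.0681) lost its call without wild type 4 or mARF8 3, highest adjusted p in brackets. IAA13 (0.103) lost its call without wild type 2 or 4 or mARF8 3 or 4. UMAMIT42 (0.205) lost its call without wild type 1, 2, 3 or 4 or mARF8 2, 3 or 4. AT1G14120 (0.105) lost its call without wild type 2 or 4 or mARF8 2 or 3. GILT (0.152) and AT1G28660 (0.133) lost their calls without wild type 1, 2 or 4 or mARF8 1, 2, 3 or 4. MSRB9 (0.0693) lost its call without mARF8 3.

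Between arf6arf8 and mARF8 gynoecia, 54 genes changed in opposite directions and 7 in the same direction. Higher in arf6arf8 and lower in mARF8 were 24, against 4.51 for independent lists, and lower in arf6arf8 and higher in mARF8 were 30, IAA7 among them, against 2.74. There were 3 genes higher in both, against 3.40 for independent lists of those sizes, and 4 lower in both, against 3.63 (covariance of the fold changes across genes 0.0160, and 0.0225 simulated). With the wild-type libraries divided, 1 to 5 genes changed in the same direction, and the low-numbered libraries alone gave 1 in the same and 2 in opposite directions. The same and opposite counts were 20 and 41 without wild type 1, 6 and 27 without wild type 2, 3 and 24 without wild type 4, 4 and 27 without mARF8 2, 3 and 17 without mARF8 3, 4 and 37 without arf6arf8 1 and 3 and 36 without arf6arf8 2.

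In axr3 gynoecia, carpel and ovule genes were lower than in wild type, and jasmonate and secondary wall genes were higher. Among 21 carpel genes, 9 fell (10 lower adjusted over the list alone, camera adjusted p = 9.54e-07, or 0.0336 with an estimated correlation). SHP1 was at 74.0 ± 6.41 against 148 ± 6.11 CPM (log2 fold change −1.01, SE 0.08, adjusted p = 5.43e-08), and NTT (AT3G57670), a zinc finger gene of the transmitting tract, was at 22.4 ± 4.72 against 57.0 ± 5.05 CPM (log2 fold change −1.32, SE 0.12, adjusted p = 6.62e-07). Among 29 Aux/IAA and GH3 genes, 3 rose and 9 fell (5 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0577). IAA7 was at 4.12 ± 1.70 against 34.4 ± 7.24 CPM (log2 fold change −3.16, SE 0.25, adjusted p = 7.4e-08), and IAA13 fell by 0.44 (SE 0.08, adjusted p = 0.000689). Among 9 ovule genes, 1 rose and 4 fell (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 5.66e-05, or 0.259 with an estimated correlation). TT12 (AT3G59030), a transporter gene of seed coat proanthocyanidins, fell by 5.06 (SE 0.38, adjusted p = 4.02e-08), and the homeobox gene WUS (AT2G17950) rose by 1.64 (SE 0.22, adjusted p = 5.54e-05). Among 15 jasmonate response genes, 8 rose (10 higher adjusted over the list alone, camera adjusted p = 2.38e-05, or 0.423 with an estimated correlation). The jasmonate response count was 5 without wild type 2 or axr3 1. JAZ5 (AT1G17380) rose by 2.11 (SE 0.36, adjusted p = 0.000454) and JAZ10 (AT5G13220) by 1.21 (SE 0.15, adjusted p = 1.69e-05). Among 21 jasmonate synthesis genes, 9 rose (10 higher adjusted over the list alone, camera adjusted p = 3.57e-05, or 0.331 with an estimated correlation). The jasmonate synthesis count was 5 without axr3 2. LOX2 was at 1805 ± 292 against 656 ± 180 CPM (log2 fold change 1.46, SE 0.19, adjusted p = 4.09e-05), and AOC1 rose by 1.91 (SE 0.24, adjusted p = 2.57e-05). Among 19 secondary wall genes, 12 rose (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.69e-07, or 0.157 with an estimated correlation). The xylem peptidase gene XCP2 (AT1G20850) rose by 1.70 (SE 0.28, adjusted p = 0.000359) and the laccase gene LAC17 (AT5G60020) by 1.51 (SE 0.24, adjusted p = 0.000250). Among 28 expansin and xyloglucan hydrolase (XTH) genes, 6 rose and 4 fell (8 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.215). EXPA9 (AT5G02260) was at 25.3 ± 5.84 against 1.83 ± 0.333 CPM (log2 fold change 3.74, SE 0.19, adjusted p = 3.11e-10), and XTH24 (AT4G30270) rose by 4.48 (SE 0.51, adjusted p = 7.67e-06).

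The highest genes of axr3 gynoecia were absent or nearly absent from wild type. MPC (AT3G19350), the fatty acyl reductase gene FAR4 (AT3G44540), AT3G50990 and AT5G51500 had no count there and were at least 126-fold (adjusted p = 0.00331), 163-fold (adjusted p = 2.85e-05), 179-fold (adjusted p = 6.36e-07) and 120-fold (adjusted p = 0.000746) higher, and the aminotransferase gene TAT3 (AT2G24850) was higher by a ratio of 474 (95% counting interval 84.5 to 18757, adjusted p = 9.94e-07). AT1G72290 was at 1.36 ± 0.582 against 187 ± 52.0 CPM (log2 fold change −7.03, SE 0.40, adjusted p = 1.36e-09), the xylosidase gene BXL3 (AT5G09730), the abscisic acid hydroxylase gene CYP707A2 (AT2G29090) and AT4G33600 fell by 5.91 (SE 0.56, adjusted p = 8.1e-07), 5.99 (SE 0.64, adjusted p = 3.24e-06) and 6.04 (SE 0.36, adjusted p = 2.81e-09), and BETAG4 was lower by a ratio of 382 (95% counting interval 131 to 1857, adjusted p = 2.12e-08). IAA17, which includes the transgene, was at 74.0 ± 7.57 against 11.2 ± 2.65 CPM (log2 fold change 2.71, SE 0.17, adjusted p = 4.43e-09). In all, 2929 of 18616 genes changed, 1614 higher and 1315 lower. Among low-numbered libraries 1105 genes changed and among high-numbered ones 1445. Beside arf6arf8 gynoecia, 758 genes changed in the same direction and 95 in opposite directions, IAA7 and SHP1 among those lower in both. There were 412 genes higher in both, against 99.8 for independent lists of those sizes, and 346 lower in both, against 65.4 (covariance of the fold changes across genes 0.182, and 0.0222 simulated). With the wild-type libraries divided, 266 to 344 genes changed in the same direction. The same and opposite counts were 512 and 63 without wild type 3, 504 and 59 without wild type 4, 291 and 40 without arf6arf8 1 and 335 and 28 without arf6arf8 2.

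In arf6axr3 gynoecia fewer genes differed from wild type. Among 29 Aux/IAA and GH3 genes, 1 rose and 4 fell (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 4.45e-05, or 0.102 with an estimated correlation). The Aux/IAA and GH3 count was 0 higher without wild type 2 or arf6axr3 3 or 4, and 1 lower without arf6axr3 4 and 2 lower without wild type 2 or 3 or arf6axr3 2 or 3. IAA7 was at 10.7 ± 2.42 against 34.4 ± 7.24 CPM (log2 fold change −1.72, SE 0.21, adjusted p = 0.000179), and IAA1 (AT4G14560) fell by 1.07 (SE 0.22, adjusted p = 0.0155). Among 21 carpel genes, 3 fell (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00297, or 0.106 with an estimated correlation). IND was at 1.25 ± 0.832 against 9.55 ± 3.70 CPM (log2 fold change −3.06, SE 0.39, adjusted p = 0.000329), and SHP1 at 87.4 ± 4.17 against 148 ± 6.11 CPM (log2 fold change −0.76, SE 0.08, adjusted p = 2.59e-05). Among 21 jasmonate synthesis genes, 3 rose (4 higher adjusted over the list alone, camera adjusted p = 0.000262, or 0.423 with an estimated correlation). The jasmonate synthesis count was 1 without wild type 2 or 4 or arf6axr3 2. AOC1 rose by 1.38 (SE 0.24, adjusted p = 0.00487) and LOX2 by 0.90 (SE 0.19, adjusted p = 0.0216). Of 15 jasmonate response genes edgeR called 0, with 5 higher and 0 lower at unadjusted p < 0.05 and 1 higher and 0 lower by DESeq2 (median log2 fold change 0.20, camera adjusted p = 0.00128, or 0.553 with an estimated correlation). Of 19 secondary wall genes edgeR called 0, with 8 higher and 1 lower at unadjusted p < 0.05 and 1 higher and 0 lower by DESeq2 (median log2 fold change 0.35, camera adjusted p = 0.000935, or 0.423 with an estimated correlation). Of 9 SAUR genes edgeR called 0, with 0 higher and 4 lower at unadjusted p < 0.05 and 0 higher and 0 lower by DESeq2 (median log2 fold change −0.40, camera adjusted p = 0.0248, or 0.460 with an estimated correlation). Among 31 cell cycle genes, 1 fell, but the median log2 fold change was 0.098 (1 lower adjusted over the list alone, camera adjusted p = 0.00588, or 0.553 with an estimated correlation). The cell cycle count was 0 without wild type 2 or 3 or arf6axr3 3 or 4. The tapetum list (camera adjusted p = 0.522, 11 genes tested) stood 1.79 in arf6axr3 4 and −1.57 to −1.06 in the others relative to wild type (438 CPM in total, against 51.0 to 62.1), so anther material in arf6axr3 4 is not excluded. sks14 (AT1G55560), PYD4 (AT3G08860), AT1G14120, IGMT5 (AT1G76790) and the arginase gene ARGAH2 (AT4G08870) rose by 3.76 (SE 0.62, adjusted p = 0.00307), 3.61 (SE 0.52, adjusted p = 0.00113), 2.81 (SE 0.50, adjusted p = 0.00505), 2.60 (SE 0.46, adjusted p = 0.00468) and 2.53 (SE 0.40, adjusted p = 0.00249). ARF6, AT2G43610, GAD5 (AT3G17760) and BXL3 fell by 3.10 (SE 0.10, adjusted p = 1.62e-12), 2.51 (SE 0.22, adjusted p = 6.7e-06), 2.35 (SE 0.56, adjusted p = 0.0398) and 2.28 (SE 0.36, adjusted p = 0.00219), and IAA17 rose by 1.45 (SE 0.17, adjusted p = 0.000166). In all, 320 of 18616 genes changed, 199 higher and 121 lower, and DESeq2 gave 507. The high-numbered libraries alone, which hold the 4 arf6axr3 libraries, gave 115 genes, line 15-5 alone 85, and the library number as a covariate, chosen after seeing the data, 170. The count was 143 without wild type 2, 177 without arf6axr3 2, 185 without arf6axr3 4 and 195 without arf6axr3 3. IAA1 (0.0725) lost its call without arf6axr3 2 or 4, highest adjusted p in brackets. LOX2 (0.0749) lost its call without wild type 2 or 4 or arf6axr3 2. GAD5 (0.185) lost its call without wild type 2, 3 or 4 or arf6axr3 1, 2, 3 or 4.

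Set against axr3 itself, arf6axr3 gynoecia had carpel and ovule transcripts at higher levels and secondary wall and jasmonate transcripts at lower levels. Of 21 carpel genes, 7 rose and 1 fell (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000340, or 0.102 with an estimated correlation). NTT was at 59.6 ± 7.94 against 22.4 ± 4.72 CPM (log2 fold change 1.38, SE 0.12, adjusted p = 6.23e-07), and IND fell by 2.78 (SE 0.40, adjusted p = 0.000166). Of 9 ovule genes, 4 rose and 1 fell (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.48e-05, or 0.210 with an estimated correlation). TT12 was at 4.72 ± 0.695 against 0.196 ± 0.175 CPM (log2 fold change 4.50, SE 0.39, adjusted p = 4.93e-07), and the MADS gene TT16 (AT5G23260) rose by 2.06 (SE 0.33, adjusted p = 0.000592). Of 19 secondary wall genes, 7 fell (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.000236, or 0.355 with an estimated correlation). The secondary wall count was 3 without axr3 2 and 4 without axr3 1 or arf6axr3 1 or 2. The lignin regulator gene MYB85 (AT4G22680) was lower by a ratio of 18.1 (95% counting interval 5.81 to 91.4, adjusted p = 0.00175), and the cellulose synthase gene CESA4 (AT5G44030) fell by 0.57 (SE 0.12, adjusted p = 0.00613). Of 15 jasmonate response genes, 2 fell (2 lower adjusted over the list alone, camera adjusted p = 0.00752, or 0.618 with an estimated correlation). The jasmonate response count was 1 without axr3 1, 2 or 4 or arf6axr3 1, 3 or 4. Of 21 jasmonate synthesis genes, 2 fell (2 lower adjusted over the list alone, camera adjusted p = 0.0259, or 0.605 with an estimated correlation). That count was 1 without axr3 2 or 4. IAA7 rose by 1.44 (SE 0.27, adjusted p = 0.00233) and IAA19 (AT3G15540) fell by 1.75 (SE 0.41, adjusted p = 0.0121). Of 8 dehiscence and pollen separation genes, 3 fell (3 lower adjusted over the list alone, camera adjusted p = 0.0260, or 0.210 with an estimated correlation). The polygalacturonase gene ADPG1 (AT3G57510) fell by 2.88 (SE 0.34, adjusted p = 1.61e-05) and SWEET13 (AT5G50800) by 3.48 (SE 0.64, adjusted p = 0.00177).

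AT1G72290, AT4G33600, AT5G44440 and CYP707A2 rose in arf6axr3 against axr3 by 6.61 (SE 0.41, adjusted p = 5.47e-09), 5.58 (SE 0.38, adjusted p = 2.01e-08), 5.19 (SE 0.38, adjusted p = 5.16e-08) and 4.71 (SE 0.71, adjusted p = 0.000280), and BETAG4 was higher by a ratio of 105 (95% counting interval 35.8 to 513, adjusted p = 5.59e-06). FAR4 and AT5G51500 had no count in arf6axr3 and were at least 169-fold (adjusted p = 4.65e-05) and 124-fold (adjusted p = 0.00135) lower, and MPC, CYP71B23 (AT3G26210) and AT3G50990 were lower by ratios of 394 (95% counting interval 70.1 to 15600.0, adjusted p = 0.00633), 317 (95% counting interval 87.3 to 2626, adjusted p = 9.05e-07) and 279 (95% counting interval 76.8 to 2312, adjusted p = 1.39e-06). ARF6 and IAA17 fell by 3.02 (SE 0.10, adjusted p = 2.45e-12) and 1.25 (SE 0.15, adjusted p = 2.93e-05). In all, 1593 of 18616 genes changed, 675 higher and 918 lower. Of the 2929 genes changed in axr3 against wild type, 235 changed the same way in arf6axr3 against wild type, against 17.3 higher and 8.55 lower for independent lists (covariance of the fold changes across genes 0.129, and 0.0229 simulated, with 54 to 116 when the wild-type libraries were divided). That 235 was 114 without wild type 2, 137 without arf6axr3 2, 137 without arf6axr3 4, 150 without arf6axr3 3 and 156 without wild type 4. The high-numbered libraries alone gave 721 genes, line 15-5 alone 797 and line 25-2 alone 765.

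**Figure D3:**
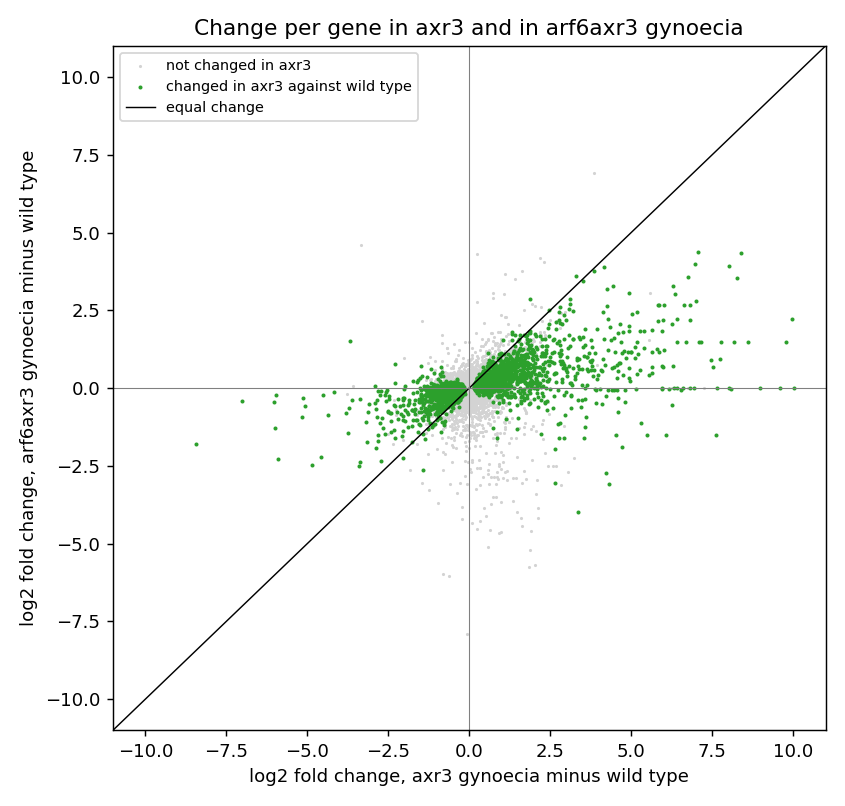
Log2 fold change against wild type per gene in axr3 gynoecia (horizontal axis) and in arf6axr3 gynoecia (vertical axis). Both axes use the same wild-type libraries, and the test called 2929 genes on the horizontal axis and 320 on the vertical axis.

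A test of the difference between tissues compared the effect of arf6arf8 in stamens with its effect in gynoecia. Tissue goes with flower stage here, stage 11 in stamens and stage 12 in gynoecia, so tissue and stage cannot be told apart. Of 22 jasmonate response genes, 7 had the lower effect in stamens (13 lower adjusted over the list alone, camera adjusted p = 2.58e-09, or 0.102 with an estimated correlation). Of 21 jasmonate synthesis genes, 1 had the higher effect in stamens and 5 the lower effect in stamens (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 6.89e-07, or 0.102 with an estimated correlation). That count was 0 higher without arf6arf8 gynoecia 1 or 2 or arf6arf8 stamens 1, and 3 lower without arf6arf8 stamens 1. Of 33 expansin and XTH genes, 7 had the lower effect in stamens (8 lower adjusted over the list alone, camera adjusted p = 0.0257, or 0.379 with an estimated correlation). The expansin and XTH count was 2 without arf6arf8 stamens 1 and 4 without arf6arf8 gynoecia 1, wild type stamens 1 or arf6arf8 stamens 2. Of 28 photosynthesis genes, 4 had the lower effect in stamens (11 lower adjusted over the list alone, camera adjusted p = 3.28e-09, or 0.553 with an estimated correlation). The photosynthesis count was 1 without arf6arf8 gynoecia 2 or arf6arf8 stamens 1. Of 11 flavonoid synthesis genes, 3 had the lower effect in stamens (3 lower adjusted over the list alone, camera adjusted p = 0.0116, or 0.571 with an estimated correlation). Of 26 late pollen genes, 2 had the lower effect in stamens (6 lower adjusted over the list alone, camera adjusted p = 1.78e-05, or 0.553 with an estimated correlation). The late pollen count was 0 without arf6arf8 gynoecia 2 or arf6arf8 stamens 1 and 1 without wild type gynoecia 1, 2, 3 or 4, arf6arf8 gynoecia 1, wild type stamens 1, 2 or 3 or arf6arf8 stamens 2. Of 9 ovule genes, 1 had the higher effect in stamens (3 higher adjusted over the list alone, camera adjusted p = 0.0456, or 0.571 with an estimated correlation). The ovule count was 0 without arf6arf8 stamens 1 or 2 and 2 without wild type gynoecia 1 or wild type stamens 2. Of 32 Aux/IAA and GH3 genes, 2 had the higher effect in stamens (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0260, or 0.540 with an estimated correlation). The Aux/IAA and GH3 count was 4 without wild type stamens 2. Of the 20665 genes tested here, 16924 passed the filter in both tissues, with 20 of the late pollen genes. A gene absent from a tissue restates its effect in the other. AT3G26140 stood at 9.96 and 4.68 CPM in mutant and wild-type stamens and 0.375 and 136 in gynoecia (adjusted p = 2.89e-10), and AT4G33600 was also among the highest (adjusted p = 0.0420). MIF2 stood at 0 and 24.5 CPM in mutant and wild-type stamens and 0.543 and 0.183 in gynoecia (adjusted p = 3.25e-05), with UGT85A3 (adjusted p = 0.00124) and AT3G17580 (adjusted p = 0.000259) also lowest. In all, 1374 genes differed, 592 with the higher effect in stamens (43.1%) and 782 with the lower. The higher share was 25.9% with median-of-ratios size factors and 26.4% with DESeq2. The low-numbered libraries alone gave 542 genes, no arf6arf8 library has a high number, and fitting only the groups compared gave 2681. The count was 608 without arf6arf8 stamens 1, 666 without arf6arf8 gynoecia 1, 696 without arf6arf8 gynoecia 2 and 762 without arf6arf8 stamens 2. AT4G33600 (1.00) lost its call without wild type gynoecia 3 or 4, arf6arf8 gynoecia 2, wild type stamens 1, 2 or 3 or arf6arf8 stamens 2, highest adjusted p in brackets.

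The same test for mARF8 set its stamen effect against its gynoecium effect. Among 26 cuticle genes, 17 had the higher effect in stamens and 2 the lower effect in stamens (18 higher and 2 lower adjusted over the list alone, camera adjusted p = 6.89e-07, or 0.355 with an estimated correlation). The cuticle count was 1 lower without wild type gynoecia 2 or 3, mARF8 gynoecia 1 or 2, wild type stamens 1 or 3 or mARF8 stamens 1, 2 or 4. Among 26 late pollen genes, 8 had the lower effect in stamens (8 lower adjusted over the list alone, camera adjusted p = 8.42e-08, or 0.445 with an estimated correlation). The late pollen count was 13 without mARF8 stamens 3. Among 31 cell cycle genes, 9 had the lower effect in stamens (10 lower adjusted over the list alone, camera adjusted p = 0.00106, or 0.460 with an estimated correlation). Among 28 photosynthesis genes, 5 had the higher effect in stamens (5 higher adjusted over the list alone, camera adjusted p = 0.00297, or 0.810 with an estimated correlation). The photosynthesis count was 3 without wild type stamens 3 or mARF8 stamens 2, 9 without mARF8 gynoecia 2 and 13 without mARF8 stamens 4. SWEET14 stood at 0.359 and 15.7 CPM in mutant and wild-type stamens and 1.20 and 0.640 in gynoecia (adjusted p = 1.84e-05), and the glucosinolate synthesis gene MAM1 (AT5G23010) at 0.494 and 36.5 CPM in mutant and wild-type stamens and 0.130 and 0.0523 in gynoecia (adjusted p = 0.0169). ABCB14 (AT1G28010) (adjusted p = 0.000368) was also among the lowest, and AT1G06100 (adjusted p = 0.00263), AT3G14520 (adjusted p = 0.00208) and AT5G64120 (adjusted p = 0.0462) were the highest. In all, 5338 genes differed, 2918 with the higher effect in stamens (54.7%) and 2420 with the lower. The higher share was 68.3% with upper-quartile factors, which moved the median of all genes by 0.112, and 43.7% with DESeq2. Low-numbered libraries alone gave 840 genes, and line 3B alone gave 3289. Tissue goes with flower stage here, and also with line, since only the stamens include line 4B and the T1 pool. AT5G64120 (0.159) lost its call without wild type gynoecia 1 or 4, mARF8 gynoecia 1, 2 or 3, wild type stamens 1, 2 or 3 or mARF8 stamens 1, 2 or 4, highest adjusted p in brackets. MAM1 (0.195) lost its call without mARF8 gynoecia 1 or 3.

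**Figure D4:**
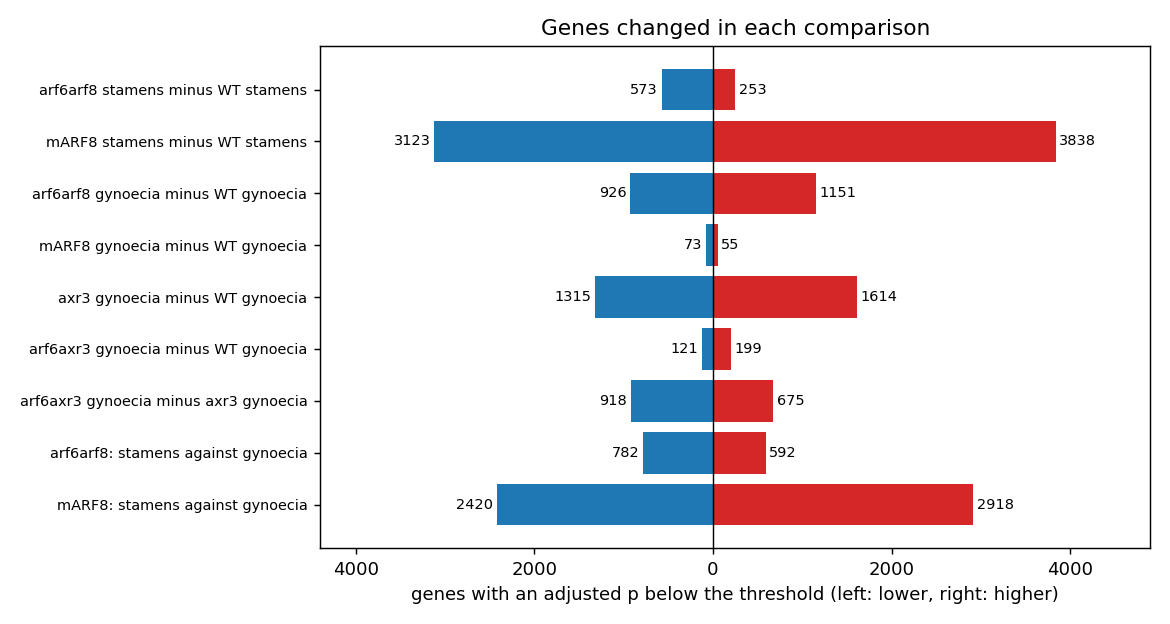
Number of genes changed (horizontal axis) in each comparison (vertical axis), split by direction. Group sizes differ from 2 to 4 libraries, so the bars are not a ranking of effect.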

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

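The tests chosen only after their result was seen are the pollen share and stamen stage tests, the library number and IAA17 tests and the counting interval of MIR167a. Of 340 groups of 4 values tested with Dixon's gap ratio, 22 (6.47%) held a library far from the other 3, and chance alone marks about 1 in 20. Values below give that library against the range of the others.

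In wild-type gynoecia, library 1 had TAT3 at 0.0996 CPM against 0, CER4 at 150 CPM against 93.4 to 99.2, ARF8 at 406 CPM against 371 to 372 and LAC17 at 4.98 CPM against 2.23 to 2.40. Library 2 had sks14 at 0.663 CPM against 0 to 0.109. Library 4 had AT4G08093 at 0.328 CPM against 0 and STK at 138 CPM against 129 to 131. In arf6axr3 gynoecia, library 1 had AT2G43610 at 2.95 CPM against 5.21 to 5.41 and TT16 at 11.5 CPM against 7.79 to 8.36. Library 3 had MPC at 0.137 CPM against 0. In axr3 gynoecia, library 1 had PPME1 at 43.4 CPM against 0 to 6.27. Library 3 had SWEET13 at 7.00 CPM against 1.86 to 2.20. In mARF8 gynoecia, library 4 had AT1G28660 at 0.190 CPM against 0. In mARF8 stamens, library 2 had IAA17 at 3.19 CPM against 5.06 to 5.32 and KCS6 at 1147 CPM against 668 to 747. Library 3 had MIR167d at 0.102 CPM against 0, UGT73C2 at 0.205 CPM against 0 and LTI30 at 0.102 CPM against 0. Total counts of mARF8 stamens 3 were 10.1 against 5.13 to 5.65 in units of 10 to the power 6. On the list means relative to wild type (log2 CPM), mARF8 gynoecia 2 stood at 0.17 for the expansin and XTH list against −0.08 to −0.05, axr3 gynoecia 3 at 0.51 for the jasmonate response list against 0.91 to 0.99, and arf6axr3 gynoecia 4 at 1.79 for the tapetum list against −1.57 to −1.06.

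By an interaction test, 1374 gene effects differed between tissues for arf6arf8 and 5338 for mARF8. For arf6arf8 the named genes had adjusted p = 2.89e-10 (AT3G26140), 0.00858 (TT12), 0.0420 (AT4G33600), 0.00124 (UGT85A3), 0.000259 (AT3G17580) and 3.25e-05 (MIF2). For mARF8 they had adjusted p = 0.00263 (AT1G06100), 0.00208 (AT3G14520), 0.0462 (AT5G64120), 0.000368 (ABCB14), 1.84e-05 (SWEET14) and 0.0169 (MAM1).

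Late pollen transcripts were lower in mARF8 stamens. A lower share of pollen RNA as the whole cause would raise genes of other tissues alike, and the median log2 fold change of the clock list lay −0.891 from that of the secondary wall, cuticle and photosynthesis lists (spread 0.640). Clock expression in pollen was not tested, so a lower share stays open. Without each mARF8 library in turn the lowest count of late pollen genes lower was 14, which argues against 1 aberrant mARF8 library, although it was 10 without wild type 1 or 3. Younger stamens at the same bud length stay open, since the tapetum list also stood higher (median 0.830, spread 1.72) and no library of another stage was compared. Line and handling also stay open, since heat shock means followed the order of the late pollen fall. The late pollen list also stood lower in arf6arf8 stamens (median −0.64).

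Gynoecia of arf6axr3 stood nearer to wild type than those of axr3, with root mean square differences in log2 CPM between their libraries and those of wild type of 0.407 to 0.520 against 0.621 to 0.788. Among high-numbered libraries alone, 45.3% as many genes changed between arf6axr3 and axr3, which argues against low-numbered against high-numbered libraries as the whole cause. Less IAA17 transcript in arf6axr3, with a log2 fold change of −1.25 (SE 0.15), cannot be told apart from the loss of ARF6, because no arf6 library has as much IAA17 transcript as axr3. Both stay open, as does the difference between lines.

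The MIR167a locus was higher in arf6arf8 stamens and gynoecia, although in stamens the call was lost without wild type 1, 2 or 3 or arf6arf8 1 or 2 (adjusted p up to 0.276). Reads from neighbouring genes would raise a neighbour in both tissues, and the highest log2 fold change that a neighbour reached in both was −0.084 (DMC1 at 0.61 in stamens, APS1 at −0.15 and 0.0059), which argues against it. The lowest arf6arf8 library had 2.68 times the CPM of the highest wild-type library in stamens (lower end of the 95% counting interval 1.55) and 29.5 times in gynoecia (12.5), which argues against chance in few reads. Spread between libraries stays open in stamens, where the log2 fold change, 2.02 (SE 0.44) with all libraries, was 1.70 to 2.34 without 1. In gynoecia the call held without each library in turn (adjusted p up to 1.57e-05). A change in transcription and a change in processing of the transcript may each give such a rise, and neither was tested here.

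Other splits of the same libraries into groups of the same sizes were refitted. Only 1 of 35 splits, the real one, called as many genes for mARF8 stamens (6961, highest other 6827), mARF8 gynoecia (128 and 13), axr3 gynoecia (2929 and 2), arf6axr3 gynoecia against wild type (320 and 30) and against axr3 (1593 and 74). That is the smallest share 35 splits can give. The 6827 came from the 3 wild-type libraries joined with mARF8 stamens 3, which lies between the groups, so the label of that library is barely tested. For the tissue difference of mARF8, 2 of 50 splits called as many genes (5338, highest other 5915), a share under 0.05 of the splits drawn. The 3 highest other splits all join the 3 wild-type stamen libraries with mARF8 stamens 3 and divide the gynoecia in different ways, so this count follows the stamen libraries and does not test the gynoecium labels.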

How the results depend on the processing

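Settings by library number and line 3B for the tissue difference were chosen after seeing the data. Of the log2 fold changes of named genes under all alternatives other than leaving out a library, 1949 kept their direction and side of the threshold, 127 lost their call, 8 gained one and 8 changed sign. Without single libraries the numbers were 1434, 144, 1 and 10. With median-of-ratios factors and with the stricter filter 213 of 213 and 198 of 198 kept both. Leaving aside subsets by library number, calls of genes in the report lost under 1 or more of these were ANN6, ARF6, AT5G64120 and MIR167a for mARF8 stamens, TBL29 for arf6arf8 gynoecia, GILT and UMAMIT42 for mARF8 gynoecia, AT5G51500 for axr3 gynoecia, AOC1, ARGAH2, AT1G14120, BXL3, GAD5, IAA1, IGMT5, LOX2 and sks14 for arf6axr3 gynoecia, AT5G51500, CESA4, IAA19 and MPC for arf6axr3 against axr3, AT4G33600 for the arf6arf8 tissue difference and AT5G64120 and MAM1 for the mARF8 tissue difference. The list test called 54 pairs with the preset correlation and 1 with an estimated one.

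The number of genes changed was 826 for arf6arf8 stamens, 6961 for mARF8 stamens, 2077 for arf6arf8 gynoecia, 128 for mARF8 gynoecia, 2929 for axr3 gynoecia, 320 for arf6axr3 gynoecia, 1593 for arf6axr3 against axr3, 1374 for the arf6arf8 tissue difference and 5338 for the mARF8 tissue difference. The DESeq2 Wald test gave 1375 for arf6arf8 stamens, 335 for mARF8 gynoecia and 507 for arf6axr3 gynoecia. Fitting only the groups compared gave 3530 for arf6arf8 stamens and 2681 for the arf6arf8 tissue difference. Low-numbered libraries only gave 287 for arf6arf8 stamens, 1325 for mARF8 stamens, 1315 for arf6arf8 gynoecia, 3 for mARF8 gynoecia, 1105 for axr3 gynoecia, 542 for the arf6arf8 tissue difference and 840 for the mARF8 tissue difference. There, the log2 fold change turned for IAA17 in mARF8 gynoecia to −0.21 (from 0.11, adjusted p = 0.809), ARF6 in axr3 gynoecia to 0.0054 (from −0.079, adjusted p = 0.990) and ARF8 in axr3 gynoecia to −0.058 (from 0.016, adjusted p = 0.884). With high-numbered libraries only, the count was 1 for mARF8 gynoecia, 1445 for axr3 gynoecia, 115 for arf6axr3 gynoecia, 721 for arf6axr3 against axr3 and 2721 for the mARF8 tissue difference. There, the log2 fold change turned for PPME1 in arf6axr3 against axr3 to 3.31 (from −6.48, adjusted p = 0.646). The library number as a covariate gave 246 for mARF8 gynoecia and 170 for arf6axr3 gynoecia. There, the log2 fold change turned for ARF8 in axr3 gynoecia to −0.015 (from 0.016, adjusted p = 0.946) and MIR167a in arf6axr3 gynoecia to −0.30 (from 0.47, adjusted p = 0.902). The arf6axr3 line 15-5 alone gave 85 for arf6axr3 gynoecia and 797 for arf6axr3 against axr3. There, STK in arf6axr3 gynoecia turned to 0.26 (from −0.49, adjusted p = 0.881). The arf6axr3 line 25-2 alone gave 765 for arf6axr3 against axr3. There, STK in arf6axr3 against axr3 turned to −1.20 (from 0.29, adjusted p = 0.00835). Line 3B alone gave 3289 for the mARF8 tissue difference. The cause was not tested. Fewer libraries leave fewer degrees of freedom, but 3530 came without mARF8 stamens. Those lay 0.519 to 1.04 apart in root mean square log2 CPM, wild type 0.424 to 0.553. Other totals stayed within 1.5 times. Beside leaving out a library, the alternatives moved 498 list counts, 62 overlap counts and 50 higher or lower counts by over 1.5 times and left 2922, 86 and 130 within that. The 301 genes of the same direction in both stamen comparisons were 57 with low-numbered libraries only, 158 with replicate block, 526 with DESeq2 Wald test and 1644 with only the groups compared. The 758 genes in arf6arf8 and axr3 gynoecia were 252 with low-numbered libraries only. The 235 genes in axr3 and arf6axr3 gynoecia were 90 with high-numbered libraries only and 145 with library number as a covariate. The 178 genes in arf6arf8 and arf6axr3 gynoecia were 92 with library number as a covariate. Depth limits genes near 0, given as bounds. High-numbered stamen libraries, 1 of wild type and 1 of mARF8, gave no fit of their own, and the 2721 of the mARF8 tissue difference rests on them and on 1 mARF8 gynoecium library, so it carries no weight.

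Leaving out each library in turn, the number of genes changed ran from 99 to 464 for arf6arf8 stamens, 2895 to 8789 for mARF8 stamens and 753 to 2285 for arf6arf8 gynoecia. For the others it ran from 38 to 173 for mARF8 gynoecia, 2213 to 3125 for axr3 gynoecia, 143 to 373 for arf6axr3 gynoecia, 1082 to 1817 for arf6axr3 against axr3, 608 to 1374 for the arf6arf8 tissue difference and 3762 to 7157 for the mARF8 tissue difference. Where a group then held 1 library, it was assumed to vary like the other groups. Log2 fold changes that changed sign ran, for IAA17 in arf6arf8 gynoecia from −0.26 without wild type 4 to 0.017 without wild type 1 (−0.13 with all). They ran, for IAA17 in mARF8 gynoecia from −0.030 without mARF8 3 to 0.34 without mARF8 1 (0.11 with all) and MIR167a in mARF8 gynoecia from −0.020 without mARF8 4 to 0.60 without wild type 4 (0.24 with all). Others ran, for MIR167a in axr3 gynoecia from −0.69 without axr3 4 to 0.18 without axr3 1 (−0.28 with all), ARF8 in axr3 gynoecia from −0.0049 without axr3 4 to 0.050 without wild type 1 (0.016 with all) and STK in arf6axr3 against axr3 from −0.068 without arf6axr3 3 to 0.60 without arf6axr3 2 (0.29 with all). The cause was not tested.

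A block by replicate number gave 584 changed genes for arf6arf8 stamens, 257 for mARF8 gynoecia, 1442 for the arf6arf8 tissue difference and 5331 for the mARF8 tissue difference. Residuals of libraries with the same number had a median correlation of 0.165 over 7 stamen pairs (4 over 0.1, median of other pairs −0.0167) and 0.0302 over 32 gynoecium pairs (8 over 0.1, other pairs −0.00861), and 5 of 9 and 3 of 18 libraries had their best match among the same number. Stamen libraries thus lean towards pairing by number and gynoecium libraries do not, and as not every pair exceeds 0.1 the main fit has no block.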

Other observations

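Gynoecia of arf6arf8 and arf6axr3, which both carry arf6 mutations, shared lower IAA7, IND and SHP1, although IAA7 and SHP1 were also lower in axr3. Against wild type, 178 genes changed in the same direction in both and 10 in opposite directions, with 103 higher in both against 12.3 for independent lists and 75 lower in both against 6.02. With the wild-type libraries divided, 37 to 71 changed in the same direction and the covariance of the fold changes ran across 0, from −0.0322 to 0.0648. With all libraries the covariance was 0.0516, and unchanged groups simulated against shared controls gave up to 0.0262, with 0 genes called in the same direction. As no gene was changed there, that 0 does not show how many of the 178 come from shared controls. The 178 was 80 without wild type 2, 95 without arf6axr3 4, 100 without arf6arf8 1, 106 without arf6axr3 2, 107 without wild type 4 and 113 without arf6axr3 3.

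The number in the library labels went with the first residual component of the gynoecium libraries (21.4% of the residual variance, n = 18), with Pearson r = 0.854 (permutation p = 0.00509, Benjamini-Hochberg 0.0102 over both tissues) and Spearman rho = 0.837 (permutation p = 0.00769, 0.0154). Without the 2 libraries farthest from the median number r was 0.797. In stamens (n = 9) r was 0.467 (permutation p = 0.373) and rho 0.667 (permutation p = 0.146), and r without the 2 farthest 0.640. What the numbers stand for is not given.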
